A study of Danio rerio with 15 samples.

How the data were processed

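Total RNA from zebrafish (Danio rerio) melanoma and skin was measured on 15 Affymetrix zebrafish arrays. Per the labels, fish were 4 to 8 months old, RNA was extracted with Trizol, and a melanoma and the skin immediately next to it were cut out of fish of a line that carries, among other genetic changes, a mutant BRAF transgene driven by the mitf promoter. Wild-type skin was taken along the side of the body. The titles gave the groups: 6 melanoma arrays, 6 arrays of skin next to a melanoma (called mutant skin) and 3 wild-type skin arrays. A shared number in 2 titles was not taken to mean the same fish. The labels give no sex, batch or scan date.

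The deposited values are log2 values, and the authors name GCRMA, a background correction and normalization for Affymetrix arrays, without a version. The values take both signs in each array and are relative to a reference level per probe set that is not stated. The median of a probe set over the 15 arrays was 0 within 1e-06 for 0 probe sets, and the median absolute value of those medians was 0.180, so the reference was not the median of these arrays. The absolute signal level is therefore unknown, and so is which signals lie near background. Higher values stand for more signal, and melanocyte genes were higher in melanoma than in skin. The lowest value, -6.64, is the log2 of 0.01 and is a floor, reached by 89 values in 37 probe sets. Array medians were -0.30, -0.56, 0.033, 0.057, -0.13 and -0.27 in mutant skin 1 to 6, -0.14, 0.098, -0.047, -0.17, -0.095 and -0.32 in melanoma 1 to 6, and -0.13, -0.10 and 0.095 in wild-type skin 1 to 3. The number of arrays limits the precision.

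Of 15617 probe sets, 115 control probe sets were left out of the tests and 15502 were tested. 10795 of these carried exactly 1 gene symbol, 135 carried several and 4572 none. Gene IDs of 10711 probe sets matched the RefSeq gene table, which changed 1 symbol. The value of a gene was the mean of its probe sets, for 8793 genes. The gene braf had no probe set with a single symbol and gives no value.

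One linear model for the 3 groups was fitted to all arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 12 residual degrees of freedom before moderation), and 3 contrasts were tested two-sided with Benjamini-Hochberg adjustment at 0.05 within each. Errors beside log2 changes are standard errors from this fit. Errors beside group levels are SD. Gene lists were tested with camera in limma, with a preset correlation of 0.01, adjusted over the 28 lists of a comparison, 27 of which are described. Beside it stand camera with an estimated correlation and a two-sided exact permutation test of each array's list level, the mean over members of the value minus the gene's mean over all arrays. With 6 against 3 arrays this exact test has 84 arrangements and its smallest p is 0.0119. For 6 against 6 it has 924 and 0.00216. Members were counted as raised or lowered over all genes tested, and again adjusted over the list alone. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

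The groups, the tests, the 28 lists and the alternatives were fixed before the data were examined. Genes to name were fixed by rule: per comparison the 12 raised and the 12 lowered genes with the largest change among those past the threshold whose groups do not overlap, up to 4 members of each list by size of change, and mitfa, crestin, sox10, dct and dhodh. Not all of these are printed, and genes outside the rule are named as such where they appear. Values relative to a reference ruled out 3 of the choices fixed in advance: the filter on dim probe sets (log2 above 4 in 3 arrays), the mean-variance trend in eBayes, which was run as an alternative, and the choice of the probe set with the highest mean. No filter, no trend and the mean of a gene's probe sets took their place.

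After the data were seen, 4 lists were added in a family of their own, because some arrays held transcripts of other organs: oocyte genes, liver and yolk-precursor genes, exocrine pancreas enzymes and MHC class 1 and 2 genes. Settings added after the data were seen were leaving out the arrays whose oocyte level lay more than 3 log2 units above the lowest array, this level as a covariate, leaving out probe sets that match several transcripts, and the probe set with the largest SD. That limit lies in the widest gap of the levels, was set after counts under another limit had been seen, and leaves 8 arrays: 5 melanoma, 2 mutant skin and 1 wild-type skin, a lone array assumed to vary like the other groups.

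The alternatives fixed in advance were quantile normalization, centring each array on its median, array quality weights, eBayes with trend and robust, only the arrays of the 2 groups compared, the replicate number as a block, leaving out each array in turn, and the other list tests. For shared controls, 20 simulations of unchanged groups against the same 3 controls were run. Group labels were exchanged over at most 100 splits. The pipeline was tested on simulated data with independent noise of 15502 probe sets, 200 of them changed. It recovered 14.9%, 64.2% and 93.9% of the changes of log2 1, 2 and 4 for melanoma against mutant skin. It recovered 3%, 46.3% and 81.8% for melanoma against wild-type skin, and 4.5%, 52.2% and 84.8% for mutant skin against wild-type skin. False calls made up 2.5%, 6.5% and 4.1% of all calls.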

Results

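Expression was measured in 6 melanomas, in 6 pieces of mutant skin next to a melanoma and in 3 pieces of wild-type skin, 1 array each. All values below are log2 values relative to a reference per probe set, so changes between groups can be read and absolute levels cannot. The number of arrays limits the precision, and the median standard error of a change was 0.39 for melanoma against mutant skin and 0.48 for the comparisons with 3 wild-type arrays.

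The arrays held transcripts of organs other than skin. The genes of the egg coat and the oocyte, such as buc, zp3b and nanog, were high in 7 arrays: mutant skin 1, 2, 4 and 6, melanoma 6 and wild-type skin 1 and 2. The mean level of the 27 measured oocyte genes was 4.48 in melanoma 6 and -3.58 to -3.22 in melanoma 1 to 5. The other 8 arrays were not free of these transcripts: the level was -1.67 in mutant skin 5, with zp2.6 at 3.75, and -2.03 in wild-type skin 3. The yolk-precursor gene vtg2, a liver product, reached 11.20 in melanoma 6, 10.32 in mutant skin 4 and 9.72 in mutant skin 6, and the pancreatic enzyme gene ctrb.1 reached 8.18 in mutant skin 4 and 6.91 in mutant skin 1. The arrays of melanoma 1 to 5 resembled each other, with correlations across probe sets of 0.635 to 0.809 after subtraction of each probe set's mean. Melanoma 6 had correlations of -0.451 to -0.350 with these and of 0.855 with mutant skin 6. Probe sets are not independent replicates, and these correlations describe the arrays only.

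**Figure D1:**
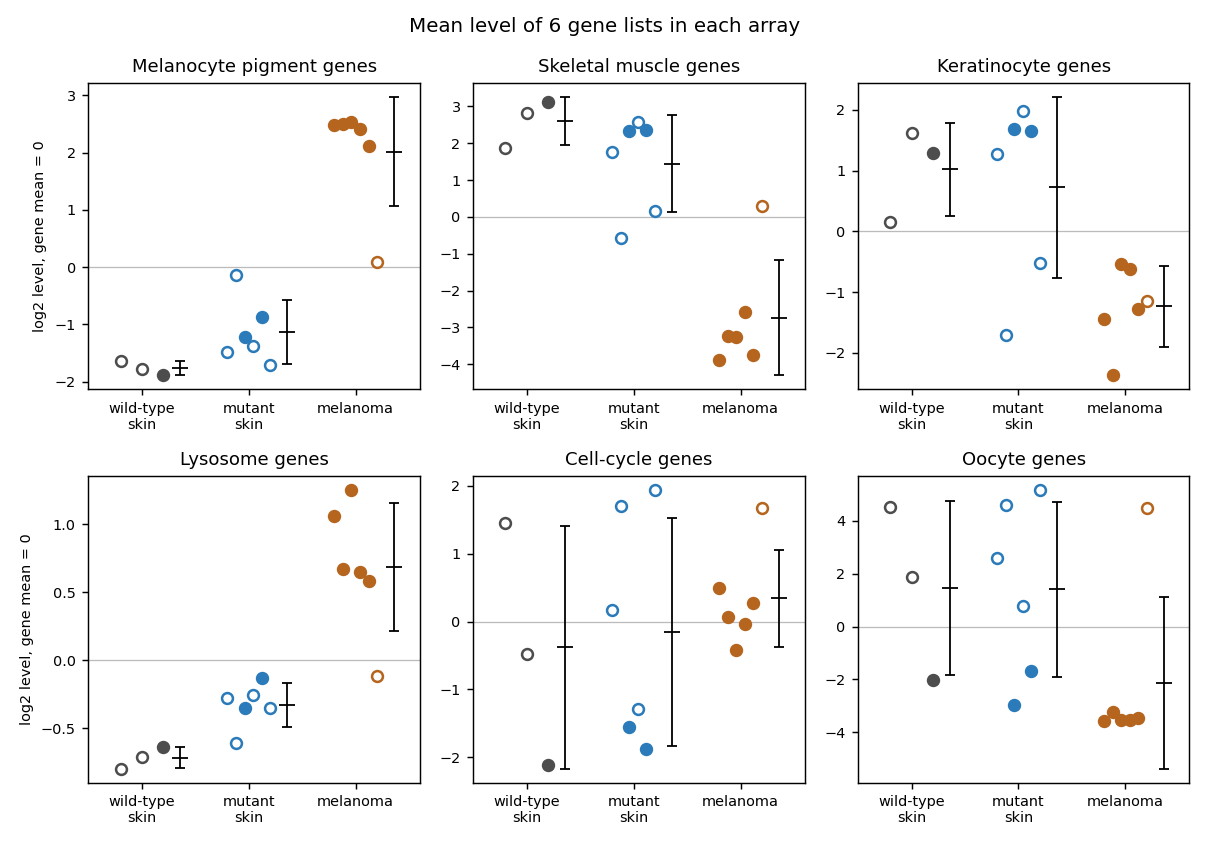
Mean log2 level of selected gene lists in each array, relative to each gene's mean over all arrays, by group; filled points are the 8 arrays without and open points the 7 arrays with high oocyte transcripts, and bars beside the points give the mean and SD. The oocyte level of melanoma 6 is 4.48, while melanoma 1 to 5 lie between -3.58 and -3.22.

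The first comparison asked how melanoma differs from the skin beside it in fish of the same line. Genes of melanocytes were much higher in melanoma, as were some of the genes of the neural crest, the embryonic source of pigment cells. The melanocyte regulator mitfa rose 56.1-fold (log2 change 5.81 ± 0.74, levels 2.30 ± 1.38 against -3.51 ± 1.61, n = 6 each, adjusted p = 0.00118), and dct, an enzyme of melanin synthesis, rose 45.7-fold (5.51 ± 0.83, adjusted p = 0.00255). The melanin enzyme gene tyr rose 17.4-fold and the melanocortin receptor gene mc1r 19.5-fold. The crest marker crestin rose 24.1-fold (4.59 ± 0.81, adjusted p = 0.00373) and the crest regulator sox10 had a log2 change of 4.32 ± 0.56 (adjusted p = 0.00118). For mitfa, dct, mc1r, crestin and sox10 all 6 melanomas lay above every mutant skin array. Genes of muscle and of the epidermis were much lower: the slow myosin gene smyhc1 had a log2 change of -5.90 ± 0.92 (adjusted p = 0.00275) and the keratin gene krt97 one of -4.02 ± 0.98 (adjusted p = 0.0163).

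Over all probe sets, 998 rose and 675 fell in melanoma against mutant skin at adjusted p under 0.05, and 932 and 664 of these changed at least 2-fold. At the gene level 652 rose and 495 fell of 8793. In 366 probe sets (2.36%) the groups did not overlap, against 0.216% by chance. Leaving out the 7 arrays with high oocyte transcripts gave 2954 probe sets, and leaving out melanoma 6 alone gave 3101. The former setting keeps 2 mutant skin arrays, and its counts and calls against mutant skin, here and below, rest on these. The larger share of rises did not hold in each setting: 1436 rose and 1518 fell without these 7 arrays, 1390 and 1436 with the oocyte covariate and 979 and 1029 without mutant skin 2. The count was 992 without mutant skin 1, and 1086, 1057, 1076 and 987 without melanoma 1, 2, 4 and 5.

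Of the 11 measured melanocyte genes 10 rose and none fell (10 adjusted over the list alone, camera adjusted p = 6.43e-09, adjusted p = 0.156 with an estimated correlation, exact adjusted p = 0.0152). Of 24 neural crest genes 9 rose, 0 fell and 15 did neither (11 adjusted over the list alone, median change 0.09, camera adjusted p = 0.0135, adjusted p = 0.599 with an estimated correlation). They included the endothelin receptor gene ednrba (8.96-fold) and dlx2a (12.6-fold). Of 6 xanthophore genes, those of yellow pigment cells, 3 rose and 0 fell (4 adjusted over the list alone, camera adjusted p = 0.0107, adjusted p = 0.156 with an estimated correlation), among them slc2a15b (8.85-fold) and the pteridine synthesis gene gch2 (6.09-fold). The pair of probe sets for gch2 changed by 0.95 and 4.27. Of 8 iridophore genes 2 rose and 1 fell, the same numbers adjusted over the list alone, and the list was not called (camera adjusted p = 0.65, median 0.46, mean -0.10). Those that rose, paics and impdh1b, are purine synthesis genes, and the one that fell, trim63a, had a log2 change of -4.31. Its relatives trim63b and trim55b, which are not on the list, changed by -4.75 and -4.85, so this fall is not particular to the iridophore list. Among other large changes, the transcription factor gene mycn rose by 4.64 ± 0.66 on the log2 scale, the transporter gene slc6a17 by 5.23 ± 0.93 and syngr1a, a synaptic vesicle gene, by 4.12 ± 0.48. The dlx2a call was lost without the arrays with high oocyte transcripts (adjusted p = 0.267) and, with adjusted p up to 0.0946, without any 1 of mutant skin 1, 2, 3, 4 or 6, melanoma 1, 2, 4 or 5 or wild-type skin 2. The impdh1b call was lost without melanoma 1, 2 or 5 (up to 0.0564). The crest list was not called without the arrays with high oocyte transcripts (camera adjusted p = 0.20), with the oocyte covariate (0.293) or with array quality weights (0.0518).

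**Figure D2:**
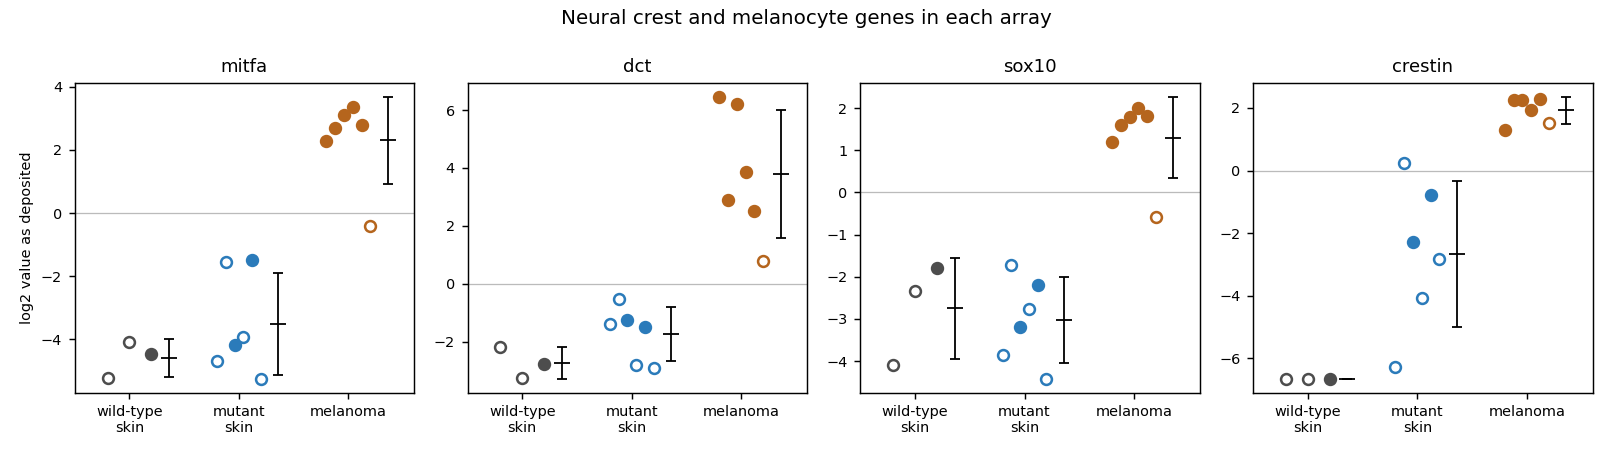
Log2 level of mitfa, dct, sox10 and crestin in each array relative to the deposited reference, by group; filled points are the 8 arrays without and open points the 7 arrays with high oocyte transcripts, and bars beside the points give the mean and SD. For mitfa melanoma 1 to 5 lie between 2.28 and 3.36, melanoma 6 at -0.40 and the wild-type arrays between -5.23 and -4.08.

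Feedback genes of the MAPK pathway, which BRAF activates, were counted as 5 raised and 1 lowered of 26 (6 and 2 adjusted over the list alone, camera adjusted p = 0.03, adjusted p = 0.599 with an estimated correlation). The phosphatase gene dusp4 rose (log2 change 3.70 ± 0.65), as did the transcription factor genes etv4 (10.4-fold) and etv5b (5.21-fold) and the inhibitor gene spry4 (7.90-fold). The gene il17rd, also an inhibitor and named outside the rule, had a change of -1.82 ± 0.45. Without melanoma 2, 4 or 5 the spry4 call was lost (adjusted p up to 0.0587), as it was with the oocyte level as a covariate (0.0548). The list was not called without the arrays with high oocyte transcripts (camera adjusted p = 0.198), with the covariate (0.803), with array quality weights (0.0675) or without mutant skin 2, 3 or 6 or melanoma 4 (up to 0.0863).

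Genes of the lysosome and the proteasome rose as groups. Of 37 lysosome genes 18 rose and 0 fell (22 adjusted over the list alone, camera adjusted p = 1.13e-09, adjusted p = 0.156 with an estimated correlation, exact adjusted p = 0.0152), led by subunits of the proton pump, atp6v1c1b (6.25-fold) and atp6ap1b (5.19-fold). Of 37 proteasome genes 15 rose and 0 fell (25 adjusted over the list alone, camera adjusted p = 2.46e-10, adjusted p = 0.355 with an estimated correlation, exact adjusted p = 0.0303), such as psmd5 (3.82-fold) and psmb2 (2.95-fold), of which psmb2 missed the threshold without the arrays with high oocyte transcripts (adjusted p = 0.0601). The counts of raised lysosome and proteasome genes were 13 and 4 without those arrays and 19 and 11 with the oocyte covariate. Of 40 chaperone genes 6 rose and 2 fell, the same adjusted over the list alone (camera adjusted p = 0.0186, adjusted p = 0.431 with an estimated correlation), with hsp90aa1.2 up 9.02-fold and canx up 3.64-fold. The chaperone call was lost without mutant skin 3 or 4 or melanoma 6 (camera adjusted p up to 0.107) and with the probe set of largest SD (0.0538). Of 17 purine synthesis genes 4 rose and 0 fell (6 adjusted over the list alone, camera adjusted p = 0.0173, adjusted p = 0.156 with an estimated correlation, exact adjusted p = 0.0152), with paics up 7.44-fold and ppat up 3.22-fold. The ppat call was lost without mutant skin 1, 3 or 4 or melanoma 1 or 4 (adjusted p up to 0.0608). Of 19 pyrimidine genes 3 rose and 1 fell (4 and 1 adjusted over the list alone, camera adjusted p = 0.0899), and the pyrimidine enzyme gene dhodh had a change of -0.18 ± 0.35 (adjusted p = 0.79). The pyrimidine list was called upward without the arrays with high oocyte transcripts (7 raised and 1 lowered, camera adjusted p = 0.00836, adjusted p = 0.197 with an estimated correlation). So it was with the oocyte covariate (8 and 1, camera adjusted p = 0.00487), with array quality weights (0.0434) and without mutant skin 2 or 6 or melanoma 3 (up to 0.0462). The gene that fell was nme2b.2, a nucleotide kinase. Its log2 change, at most -5.22, is a bound, as melanoma 1, 2 and 5 were at the floor. Of 71 ribosomal protein genes 0 passed, also adjusted over the list alone (camera adjusted p = 0.00229 upward, adjusted p = 0.69 with an estimated correlation), and the median, 0.31, was -0.0068 with the oocyte level as a covariate. The ribosomal call was lost without the arrays with high oocyte transcripts (camera adjusted p = 0.35), without mutant skin 6 (0.0758) and with array quality weights (0.0542). Of 34 transcription elongation genes 1 fell, tcea3 (-3.04 ± 0.48), the same adjusted over the list alone (camera adjusted p = 0.128). This list was called upward without the arrays with high oocyte transcripts (5 raised and 1 lowered, camera adjusted p = 0.00836, adjusted p = 0.197 with an estimated correlation). So it was with the covariate (8 and 2, camera adjusted p = 0.00537), with array quality weights (0.0249), with quantile normalization (0.045) and without mutant skin 2 or 6 (up to 0.0399).

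Of 67 cell cycle genes 5 rose and 0 fell (3 adjusted over the list alone, camera adjusted p = 0.0135, adjusted p = 0.699 with an estimated correlation), among them the replication gene mcm3 (7.07-fold). The list's level was 1.94 and 1.70 in mutant skin 6 and 2, which have high oocyte transcripts, and -1.88 to -1.28 in mutant skin 3, 4 and 5. Leaving out the 7 arrays with such transcripts gave 46 raised genes of 67. That fit keeps only mutant skin 3 and 5 of this group, whose levels were -1.55 and -1.88. The oocyte level as a covariate, which was lowest in melanoma 1 to 5, gave 53. With all but 1 array the list was not called without mutant skin 3, 4 or 5 or melanoma 6 (camera adjusted p = 0.155, 0.105, 0.186 and 0.237).

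Genes of muscle and skin were lower in melanoma as groups. Of 48 skeletal muscle genes 37 fell and 0 rose (42 adjusted over the list alone, camera adjusted p = 3.70e-31, adjusted p = 0.156 with an estimated correlation, exact adjusted p = 0.0303), with changes of -6.46 ± 1.07 for ldb3a and -5.60 ± 0.79 for tpm1, a tropomyosin gene. The muscle gene pvalb7, a parvalbumin, changed by -5.71 ± 0.72. Of 46 keratinocyte genes 18 fell and 0 rose (30 lowered and 1 raised adjusted over the list alone, camera adjusted p = 1.27e-12, adjusted p = 0.388 with an estimated correlation, exact adjusted p = 0.0788), such as ppl (-3.61 ± 0.85), a cell envelope gene, and the epithelial splicing regulator esrp2 (-3.37 ± 0.62). The count of keratinocyte genes was 34 without the arrays with high oocyte transcripts. Of 11 ionocyte and mucous cell genes 1 fell, the mucin muc5.2 (-3.19 ± 0.92), and 3 adjusted over the list alone (camera adjusted p = 0.000322, adjusted p = 0.388 with an estimated correlation). The muc5.2 call was lost without mutant skin 1, 3, 4 or 5 or melanoma 1 to 5 (adjusted p up to 0.0689) and with eBayes trend and robust (0.0555). Of 22 scale and bone genes 2 fell, twist3 (-3.23 ± 0.68) and, named outside the rule, sost (-2.82 ± 0.64), while 1 rose and 3 fell adjusted over the list alone (camera adjusted p = 0.000983, adjusted p = 0.599 with an estimated correlation). Of 43 extracellular matrix genes 3 fell and 1 rose (0 and 1 adjusted over the list alone, camera adjusted p = 0.000983 downward, adjusted p = 0.599 with an estimated correlation). The one that rose was the cartilage collagen gene col9a2 (40.7-fold). The counts of lowered ionocyte and mucous, scale and bone, and matrix genes were 8, 12 and 21 without the arrays with high oocyte transcripts. They were 7, 8 and 19 with the oocyte covariate.

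Of 69 oxidative phosphorylation genes 5 fell and 1 rose (2 and 1 adjusted over the list alone, camera adjusted p = 9.54e-05, adjusted p = 0.599 with an estimated correlation). The complex I gene ndufa3 changed by -1.64 ± 0.44 and the cytochrome oxidase gene cox6b1 rose 6.59-fold. Without the arrays with high oocyte transcripts 34 fell. The ndufa3 call was lost without mutant skin 1, 3 or 4 or melanoma 2, 3 or 4 (adjusted p up to 0.0547). Of 38 glycolysis and hypoxia genes 4 rose and 6 fell (9 and 9 adjusted over the list alone), with no call (camera adjusted p = 0.817). The log2 change of gapdh, at most -5.44, is a bound, as melanoma 1, 2 and 5 were at the floor, and rests on 1 probe set. The GAPDH control probe sets of the array went the other way, at 0.56 to 2.07 in melanoma 1 to 5, -0.99 in melanoma 6 and -2.23 to 0.62 in mutant skin, so the direction of gapdh is uncertain. The gene aldoab, the form of aldolase in muscle, changed by -5.17 ± 1.00, while pfkpa, a phosphofructokinase named outside the rule, rose 5.12-fold. The pfkpa call was lost without any 1 of mutant skin 1, 2, 3 or 6, melanoma 1 to 5 or wild-type skin 2 (up to 0.0878) and with the oocyte covariate (0.0623). Of 18 reference genes tuba1b rose (7.42-fold), the single probe set of gapdh fell and 16 did neither, the same adjusted over the list alone (camera adjusted p = 0.133).

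Markers of other cells gave smaller counts. Of 34 neural and glial genes 2 rose and 3 fell, the same adjusted over the list alone (camera adjusted p = 0.0319 downward, adjusted p = 0.599 with an estimated correlation), with the synaptic genes sypa and snap25b up 14.2-fold and 7.24-fold and the myelin gene mbpa changed by -4.18 ± 0.90. Of 30 myeloid genes 2 fell (1 adjusted over the list alone, camera adjusted p = 0.476), the lysozyme gene lyz (-3.42 ± 0.83) and the mast cell gene cpa5 (-2.85 ± 0.84). The myeloid list was called downward without the arrays with high oocyte transcripts (4 lowered and 1 raised, camera adjusted p = 0.0425, adjusted p = 0.546 with an estimated correlation). The covariate gave the same call (4 lowered, 0.000732). Of 11 lymphoid genes 1 rose, runx3 (2.16 ± 0.65), and 0 adjusted over the list alone (camera adjusted p = 0.562, median -0.17, mean 0.01). Of 25 interferon and antigen presentation genes 2 rose, isg15 (8.24-fold) and tapbp.1 (3.18-fold), and 2 adjusted over the list alone (camera adjusted p = 0.127, and 0.0428 with quantile normalization and 0.0372 with the title number as a block). Of 13 endothelial genes 1 rose and 2 fell, the same adjusted over the list alone (camera adjusted p = 0.0601). The endothelial list was called downward without the arrays with high oocyte transcripts (6 lowered and 0 raised, camera adjusted p = 0.00144, adjusted p = 0.197 with an estimated correlation). It was also called with the covariate (7 lowered, 0.000124). Quantile normalization (0.0298), centred arrays (0.0481) and array quality weights (0.023) also gave that call, as did leaving out mutant skin 2 or 6 or melanoma 3, 4 or 5 (up to 0.0463). Of 18 erythrocyte genes 0 passed, also adjusted over the list alone (camera adjusted p = 0.0186 downward, adjusted p = 0.599 with an estimated correlation). Single arrays ended the calls of cpa5 (without mutant skin 1, 4 or 5 or melanoma 1, 2, 3 or 5, adjusted p up to 0.0912), runx3 (without any 1 of mutant skin 1, 2, 3, 4 or 6, melanoma 1 to 5 or wild-type skin 2, up to 0.0928) and isg15 (without mutant skin 1 or melanoma 1 to 5, up to 0.0658). The covariate also ended that of runx3 (0.0852). The neural list was not called without mutant skin 3 or 4 or melanoma 5 or 6 (camera adjusted p up to 0.129), nor the erythrocyte list without mutant skin 3 or 4 (up to 0.0611).

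The lists of other organs stood beside these. Of 27 oocyte genes 0 passed, also adjusted over the list alone (camera adjusted p = 9.66e-07 downward, adjusted p = 0.542 with an estimated correlation). Of 20 liver genes 1 fell, rbp4 (-3.48 ± 0.80), the same adjusted over the list alone (camera adjusted p = 0.0087, adjusted p = 0.598 with an estimated correlation). Of 14 pancreas genes 3 fell, the same adjusted over the list alone (camera adjusted p = 1.77e-05, adjusted p = 0.542 with an estimated correlation): amy2a (-3.59 ± 0.96), prss1 (-3.70 ± 0.93) and ctrb.1 (-3.89 ± 1.18). These lists still differed without the arrays with high oocyte transcripts, with 3 oocyte, 5 liver and 7 pancreas genes lowered (camera adjusted p = 0.000121, 1.30e-05 and 4.75e-05, adjusted p = 0.159, 0.158 and 0.158 with an estimated correlation). Of 12 MHC class 1 and 2 genes 1 fell, mhc1zca (-3.01 ± 0.72), the same adjusted over the list alone (camera adjusted p = 0.239, 0.0434 without the arrays with high oocyte transcripts, there with adjusted p = 0.158 with an estimated correlation, and 0.0172 with the covariate). Single arrays ended the calls of amy2a (without mutant skin 1 or melanoma 1 or 4, adjusted p up to 0.0621) and ctrb.1 (without mutant skin 1, 4 or 5, melanoma 1 to 5 or wild-type skin 2 or 3, up to 0.101). With only the arrays of the 2 groups compared, dlx2a, runx3, cpa5, pfkpa and ctrb.1 missed the threshold (adjusted p = 0.0633, 0.0578, 0.0552, 0.0547 and 0.0668), as did dlx2a with the oocyte covariate (0.0877) and ctrb.1 with eBayes trend and robust (0.0508).

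The second comparison set melanoma against the skin of wild-type fish, which differ from it in genotype as well as in tissue. The crest marker crestin was at least 380-fold higher in melanoma, as all 3 wild-type arrays were at the floor (levels 1.92 ± 0.43, n = 6, and -6.64, n = 3, adjusted p = 0.000403). The melanocyte regulator mitfa rose 118-fold (log2 change 6.89 ± 0.90, adjusted p = 0.000689), dct 91.4-fold and col9a2 107-fold. The growth factor gene gdf6a rose 40.7-fold and etv4 34.1-fold. The MHC class 1 gene mhc1ufa had the largest fall of the named genes, -8.83 ± 0.34 (levels -0.45 ± 0.34 and 8.37 ± 0.63, adjusted p = 1.08e-09), and the muscle genes ckmt2a, tmem38a and pgam2 changed by -8.57 ± 1.70, -8.15 ± 1.38 and -8.09 ± 1.39.

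In all, 1157 probe sets rose and 986 fell, 1140 and 967 of them at least 2-fold, and 821 genes rose and 658 fell. The groups did not overlap in 2473 probe sets (15.95%), against 2.38% by chance. The count of 2143 was 860 without wild-type skin 2 and 848 without wild-type skin 3. Falls outnumbered rises with only the arrays of the 2 groups (1045 rose and 1198 fell), without wild-type skin 1 (884 and 992), without the arrays with high oocyte transcripts (1318 and 1554) and with the covariate (2035 and 2246). Without the arrays with high oocyte transcripts 1 wild-type array is left. The counts and calls of that setting against wild-type skin, here and below, rest on this array. The median change of all probe sets was -0.13.

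The melanocyte, lysosome and proteasome genes were raised here too. Of 11 melanocyte genes 10 rose and 0 fell (10 adjusted over the list alone, camera adjusted p = 4.18e-08, adjusted p = 0.189 with an estimated correlation). Of 6 xanthophore genes 3 rose (3 adjusted over the list alone, camera adjusted p = 0.0189, adjusted p = 0.189 with an estimated correlation), one of them csf1ra (6.54-fold), a receptor also found on macrophages. Of 37 lysosome genes 18 rose and 0 fell (26 and 1 adjusted over the list alone, camera adjusted p = 7.92e-11, adjusted p = 0.189 with an estimated correlation), with grna.1, a granulin gene, up 15.7-fold, atp6v1c1b 14.0-fold and the enzyme gene ppt1 7.28-fold. Of 37 proteasome genes 17 rose and 0 fell (23 adjusted over the list alone, camera adjusted p = 3.69e-09, adjusted p = 0.395 with an estimated correlation). The counts of raised lysosome and proteasome genes were 15 and 7 without the arrays with high oocyte transcripts and 22 and 11 with the covariate. Of 19 pyrimidine genes 5 rose and 1 fell (6 and 1 adjusted over the list alone, camera adjusted p = 0.0144, adjusted p = 0.395 with an estimated correlation), with nme3, a nucleotide kinase gene, up 16.3-fold and dhodh at -0.54 ± 0.43 (adjusted p = 0.43). Of 67 cell cycle genes 6 rose and 0 fell (2 adjusted over the list alone, camera adjusted p = 0.00527, adjusted p = 0.719 with an estimated correlation), mcm3 by 7.34-fold. Without the arrays with high oocyte transcripts 37 cell cycle genes rose and 1 fell, and the list was not called without melanoma 6 (camera adjusted p = 0.0749) or wild-type skin 3 (0.745). The pyrimidine call was lost without melanoma 6 (0.0525) or wild-type skin 3 (0.0843) and with the title number as a block (0.0733). Of 71 ribosomal genes 0 passed, also adjusted over the list alone (camera adjusted p = 0.0471 upward, adjusted p = 0.771 with an estimated correlation), and the median, 0.21, was -0.092 with the oocyte covariate. The ribosomal call was lost without the arrays with high oocyte transcripts (camera adjusted p = 0.577), without mutant skin 1, melanoma 2, 4 or 5 or wild-type skin 1 (up to 0.929), with array quality weights (0.113), with the title number as a block (0.249), with the probe set of largest SD (0.0572) and with the eBayes trend (0.0508). The call of csf1ra was lost without wild-type skin 2 or 3 (adjusted p up to 0.0822).

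Oxidative phosphorylation, muscle and epidermis genes were lower. Of 69 oxidative phosphorylation genes 42 fell and 4 rose (54 and 4 adjusted over the list alone, camera adjusted p = 5.49e-15, adjusted p = 0.395 with an estimated correlation, exact adjusted p = 0.0278), with changes of -2.66 ± 0.53 for ndufa3 and -2.38 ± 0.58 for ndufb7, both of complex I, and cox6b1 up 12.1-fold. The muscle level moved with this group, at -2.74 ± 1.56 in melanoma and 2.6 ± 0.66 in wild-type skin. Of 48 muscle genes 42 fell and 0 rose (45 adjusted over the list alone, camera adjusted p = 1.31e-29, adjusted p = 0.189 with an estimated correlation). Of 46 keratinocyte genes 20 fell and 1 rose (32 and 1 adjusted over the list alone, camera adjusted p = 3.38e-10, adjusted p = 0.395 with an estimated correlation), with krt97 and ppl at -5.23 ± 1.21 and -3.86 ± 1.04. The one that rose, krt18b, is a keratin of simple epithelia (6.18-fold). Of 11 ionocyte and mucous genes 3 fell (3 adjusted over the list alone, camera adjusted p = 0.00105, adjusted p = 0.395 with an estimated correlation), among them the mucins muc5.1 (-3.82 ± 0.90) and muc5.2 (-4.28 ± 1.12). The calls of ndufb7, ppl and muc5.2 were lost without wild-type skin 2 or 3 (adjusted p up to 0.0836, 0.115 and 0.11), krt97 and muc5.1 without wild-type skin 2 (0.0539 and 0.0778), and krt18b without wild-type skin 1 or 2 (up to 0.0674). The lowered oxidative phosphorylation, keratinocyte and ionocyte genes numbered 54, 24 and 5 without the arrays with high oocyte transcripts and 61, 33 and 7 with the covariate.

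Further lists called downward were those of neural cells, bone, matrix and blood. Of 34 neural and glial genes 9 fell and 1 rose (14 and 1 adjusted over the list alone, camera adjusted p = 8.41e-06, adjusted p = 0.395 with an estimated correlation), with the myelin gene mbpa at -6.49 ± 1.1, s100b at -3.44 ± 0.73 and the vesicle gene sypa up 14.0-fold. Of 22 scale and bone genes 2 fell (1 adjusted over the list alone, camera adjusted p = 0.00527, adjusted p = 0.617 with an estimated correlation), one of them twist3 (-3.23 ± 0.84). Of 43 matrix genes 2 fell and 1 rose, col9a2 (0 and 1 adjusted over the list alone, camera adjusted p = 0.0144, adjusted p = 0.708 with an estimated correlation). Of 18 erythrocyte genes 1 fell, the spectrin gene sptb (-3.12 ± 0.84), the same adjusted over the list alone (camera adjusted p = 0.0409, adjusted p = 0.708 with an estimated correlation). The calls of twist3 and sptb were lost without wild-type skin 2 or 3 (adjusted p up to 0.0962 and 0.124), and that of s100b without wild-type skin 3 (0.0503). The matrix list was not called without wild-type skin 3 (camera adjusted p = 0.117), nor the erythrocyte list without melanoma 1 or 6 or wild-type skin 2 or 3 (up to 0.183). The lowered neural, bone, matrix and erythrocyte genes numbered 12, 5, 8 and 6 without the arrays with high oocyte transcripts and 18, 7, 17 and 1 with the covariate.

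The other lists were not called in melanoma against wild-type skin. Of 24 neural crest genes 6 rose and 0 fell (6 and 1 adjusted over the list alone, camera adjusted p = 0.0771). Of 26 MAPK feedback genes 4 rose and 1 fell, the same adjusted over the list alone (camera adjusted p = 0.118). Of 17 purine genes 6 rose and 2 fell (8 and 3 adjusted over the list alone, camera adjusted p = 0.0822), with gart up 4.60-fold and adss1 and adsl, whose enzymes make AMP, at -4.43 ± 0.82 and -2.17 ± 0.38. The purine list levels differed in the exact test (exact adjusted p = 0.0278). Of 38 glycolysis genes 7 rose and 7 fell (8 and 9 adjusted over the list alone, camera adjusted p = 0.497), with gpib and pfkma at -6.63 ± 1.26 and -6.08 ± 1.08. Of 30 myeloid genes 2 rose and 1 fell (0 adjusted over the list alone, camera adjusted p = 0.0748), marco (7.95-fold), csf1ra and lyz (-3.28 ± 1.02). Of 25 interferon and antigen presentation genes 3 rose and 3 fell (6 and 3 adjusted over the list alone, camera adjusted p = 0.35), with isg15 up 17.5-fold and psmb9a, an immunoproteasome gene, at -2.40 ± 0.52. Of 40 chaperone genes 6 rose and 2 fell, the same adjusted over the list alone (camera adjusted p = 0.108), and of 34 elongation genes 4 rose and 2 fell, again the same (camera adjusted p = 0.0822). Leaving out the arrays with high oocyte transcripts called the elongation (8 raised and 2 lowered, camera adjusted p = 0.00697) and chaperone lists (5 and 2, 0.047) upward and the endothelial list downward (2 lowered, 0.00771). The adjusted p with an estimated correlation was 0.251, 0.296 and 0.296. The oocyte covariate gave the same calls (camera adjusted p = 0.0103, 0.0224 and 0.00105). Some fits without 1 array called the crest, MAPK and myeloid lists (down to 0.0266, 0.0303 and 0.0145), and without wild-type skin 1 the elongation and endothelial lists (0.0169 and 0.0223).

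Of 8 iridophore genes 3 rose (3 adjusted over the list alone, camera adjusted p = 0.248), of 13 endothelial genes gata2a rose (7.72-fold, 0 adjusted over the list alone, camera adjusted p = 0.099), and of 11 lymphoid genes 0 passed, also adjusted over the list alone (camera adjusted p = 0.505). Of 18 reference genes 1 rose and 1 fell, gapdh with its single probe set, the same adjusted over the list alone (camera adjusted p = 0.505 upward, median 0.12, mean -0.06). Of the lists of other organs, 0 of 27 oocyte genes, 1 of 20 liver genes (rbp4, -3.61 ± 0.98) and 0 of 14 pancreas genes fell, the same adjusted over the list alone (camera adjusted p = 0.000472, 0.362 and 0.29), with adjusted p = 0.811 for the oocyte list with an estimated correlation. Leaving out the arrays with high oocyte transcripts gave 4, 3 and 1 lowered (camera adjusted p = 0.000952, 0.00188 and 0.0311, adjusted p = 0.318, 0.318 and 0.356 with an estimated correlation). Of 12 MHC genes 1 rose, mhc2daa (37.6-fold), and 3 fell, mhc1ufa, mhc1uda (-3.34 ± 0.39, its probe sets -4.78 and -1.91) and mhc1zca (-4.76 ± 0.89), the same adjusted over the list alone (camera adjusted p = 0.197). Among single genes, the receptor gene nrp2b rose 33.6-fold. Single arrays ended the calls of gart (without wild-type skin 2 or 3, adjusted p up to 0.129), nrp2b (without wild-type skin 3, 0.0503), isg15 (without wild-type skin 1 or 2, 0.0623) and rbp4 (without wild-type skin 2 or 3, 0.0995). They also ended those of marco (without melanoma 1 to 4 or any wild-type array, up to 0.121), lyz (without mutant skin 1, melanoma 1 to 5 or any wild-type array, up to 0.164) and gata2a (without melanoma 3, 4 or 5 or any wild-type array, up to 0.143). The gata2a call was also lost without the arrays with high oocyte transcripts (0.283) and with the oocyte covariate (0.0587), that of lyz with the covariate (0.0634) and with only the arrays of the 2 groups (0.0703), and that of adsl with the title number as a block (0.0508).

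The third comparison set mutant skin, taken next to a melanoma, against wild-type skin, and found few differences past the threshold, several of them in MHC genes, which vary between fish. The class 1 gene mhc1ufa was 403-fold lower in mutant skin (log2 change -8.66 ± 0.34, levels -0.28 ± 0.46, n = 6, and 8.37 ± 0.63, n = 3, adjusted p = 1.43e-09), and mhc1uda changed by -3.19 ± 0.39 (adjusted p = 0.00137). The class 2 gene mhc2daa rose 61.4-fold (5.94 ± 0.71, adjusted p = 0.00122). The synaptic genes snap25a and vamp1a changed by -4.31 ± 0.48 and -3.00 ± 0.39, and the peptidase gene sppl2 by -3.83 ± 0.37. Genes of pigment cells did not pass: crestin was at -2.67 ± 2.33 in mutant skin and at the floor in wild-type skin (adjusted p = 0.211), and mitfa, dct and sox10 had changes of 1.08 ± 0.90, 1.00 ± 1.02 and -0.27 ± 0.68.

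**Figure D3:**
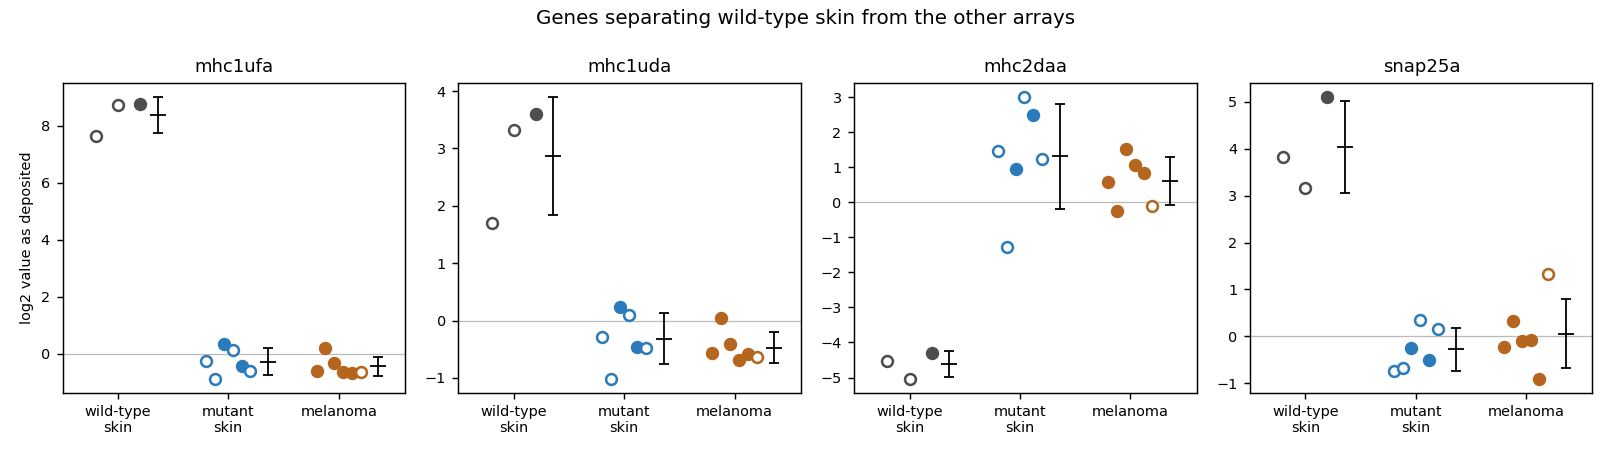
Log2 level of the MHC genes mhc1ufa, mhc1uda and mhc2daa and of the synaptic gene snap25a in each array relative to the deposited reference, by group. Filled points are the 8 arrays without and open points the 7 arrays with high oocyte transcripts. Bars beside the points give the mean and SD. For mhc1ufa the wild-type arrays lie between 7.64 and 8.77 and the 12 others between -0.88 and 0.35.

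In this comparison 4 probe sets rose and 26 fell, all at least 2-fold, and 2 genes rose and 10 fell. The groups did not overlap in 483 probe sets (3.12%), against 2.38% by chance, and the count of 30 was 54 without wild-type skin 1 and 15 without wild-type skin 3. The other genes called were copb2 (2.36 ± 0.33), a coat protein of vesicles, zic1 (-2.96 ± 0.48), a transcription factor, wls (-2.58 ± 0.32), a carrier of Wnt proteins, tsc1a (-2.23 ± 0.38), adam23a (-2.08 ± 0.38) and tubb2 (-1.76 ± 0.30). The 3 probe sets of copb2 had changes of 1.26, 0.48 and 5.35, those of wls -5.99, -1.54 and -0.20, and the pair for mhc1uda -4.71 and -1.67. Without wild-type skin 3 the adjusted p was 0.0664 for copb2, 0.188 for zic1, 0.287 for tsc1a, 0.414 for adam23a and 0.297 for tubb2. With smaller adjusted p, the calls were also lost without wild-type skin 2 for zic1, without mutant skin 1, 3, 5 or 6, melanoma 3, 4 or 5 or wild-type skin 1 or 2 for tsc1a, without mutant skin 1, 2, 5 or 6, melanoma 5 or wild-type skin 1 for tubb2, and without any 1 array but mutant skin 3 and wild-type skin 2 for adam23a. With only the arrays of the 2 groups, mhc1uda, vamp1a, zic1, tsc1a, adam23a and tubb2 missed the threshold (adjusted p = 0.0524, 0.0888, 0.204, 0.204, 0.389 and 0.317). The genes zic1 and tsc1a also missed it with quantile normalization (0.125 and 0.0886) and, with adam23a, with the eBayes trend (0.0525, 0.0699 and 0.0525), and tsc1a did with centred arrays (0.0611). With the title number as a block none of the 12 passed. Without the arrays with high oocyte transcripts 2 mutant skin arrays and 1 wild-type array were left, too few to read tests of single genes. The gene crestin passed the threshold without mutant skin 1 (adjusted p = 0.0161).

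Of the 28 lists, 6 were called in mutant skin against wild-type skin, all with adjusted p of 0.835 or 0.839 with an estimated correlation and an exact adjusted p of 0.333 or more. Oxidative phosphorylation was called downward with 0 of 69 genes past the threshold, also adjusted over the list alone (camera adjusted p = 2.25e-21), with ndufs8a and ndufab1b at -1.52 ± 0.40 and -1.36 ± 0.35. Skeletal muscle was called downward with 0 of 48 genes, also adjusted over the list alone (camera adjusted p = 2.01e-07). The neural and glial list was called downward with 2 of 34 genes, snap25a and vamp1a (7 lowered and 1 raised adjusted over the list alone, camera adjusted p = 2.63e-07). The myeloid list was called upward with 0 of 30 genes, also adjusted over the list alone (camera adjusted p = 1.11e-05), with the macrophage genes marco and c1qc at 1.88 ± 0.88 and 2.32 ± 0.94. The lysosome list was called upward with 0 of 37 genes (1 adjusted over the list alone, camera adjusted p = 0.000223), and the pyrimidine list with 0 of 19 (1 adjusted over the list alone, camera adjusted p = 0.0423), with nme3 at 2.58 ± 0.60 (adjusted p = 0.162) and dhodh at -0.35 ± 0.43 (adjusted p = 0.998). The pyrimidine call was lost with quantile normalization (0.105), array quality weights (0.218) or only the arrays of the 2 groups (0.0688), with the title number as a block (0.0509) and without mutant skin 2 or 6, melanoma 6 or wild-type skin 2 or 3 (up to 0.481). The myeloid call was lost without wild-type skin 1 (0.107).

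The other 22 lists were not called there, with camera adjusted p of 0.0696 for the melanocyte list and higher values for the others. Leaving out the arrays with high oocyte transcripts left mutant skin 3 and 5 and only 1 wild-type array, wild-type skin 3, so tests of that fit are not read. In these arrays some of the lists had higher levels in mutant skin 3 and 5 than in wild-type skin 3. Others, such as the purine and glycolysis lists, had lower levels in both or went neither way. Values are given for 5 of the higher lists, and more were higher, such as the xanthophore and matrix lists. The levels were -1.22 and -0.87 against -1.88 for melanocyte, and -1.55 and -1.88 against -2.12 for cell cycle genes. They were 1.68 and 1.65 against 1.28 for keratinocyte, and 1.49 and 1.25 against 0.58 for scale and bone genes. For proteasome genes they were 0.16 and 0.10 against -0.30. Among the members of all 22 lists 1 passed over all genes, the interferon and antigen presentation gene mhc1uda. Adjusted over the list alone, 3 interferon and antigen presentation genes, 2 purine genes and 2 chaperone genes fell, and 1 neural crest gene rose. Of the purine genes adss1 had a change of -4.07 ± 0.82 (adjusted p = 0.0984, and 0.0395 without mutant skin 5). Array quality weights brought adss1, nme3, crestin, marco, c1qc, ndufs8a and ndufab1b past the threshold, and the oocyte covariate adss1 and nme3. The median had another sign than the mean or the test for the neural crest, interferon, scale and bone, matrix and purine lists. Of the added lists, 1 of 12 MHC genes rose and 2 fell, the same adjusted over the list alone (camera adjusted p = 0.0938, median 0.15, mean -0.44), 0 of 27 oocyte, 20 liver and 14 pancreas genes passed, also adjusted over the list alone, and the pancreas list was called upward (camera adjusted p = 0.000132, adjusted p = 0.78 with an estimated correlation). The median change of all probe sets was -0.11 as deposited and 0.042 with each array centred on its median.

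All 30 probe sets that changed between mutant and wild-type skin changed the same way between melanoma and wild-type skin, 4 upward and 26 downward. Independent lists of these sizes would share 0.299 upward and 1.65 downward. Both comparisons use the same 3 wild-type arrays, which alone gives related changes. The correlation of the changes across probe sets, 0.567, was below the 0.663 of 20 simulations of unchanged groups against the same controls, and the covariance, 0.546, lay above the simulated 0.293 by 0.253. The 3 wild-type arrays are too few to split between the comparisons.

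Across the comparisons 18, 15 and 6 of the 28 lists were called with the preset correlation. With an estimated correlation 0, 0 and 0 were called, with 5, 4 and 0 at unadjusted p under 0.05. The exact test of list levels called 7, 12 and 0, with 10, 13 and 1 at unadjusted p under 0.05. For melanoma against mutant skin the exact test thus called fewer lists than camera, and its p is printed above mostly for lists it called. Without the arrays with high oocyte transcripts 2, 0 and 0 were called with an estimated correlation, the 2 being the melanocyte and the ionocyte and mucous lists of melanoma against mutant skin (adjusted p = 0.0432 each).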

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

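The tests of other organs' transcripts, of melanoma 6, of the MHC genes' neighbours and probe sets, of muscle and of the splits of the arrays were chosen after the result was seen, and those of melanoma 6 as a skin sample, of the MHC neighbours, of the MHC probe sets and of muscle were altered after a first outcome.

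Each list level and named gene was checked for a single array far from the other 5 in the groups of 6. Of 233 groups 35 stood out, where chance gives 11.65. Melanoma 6 accounted for 27 of them. Its list levels were 0.092 for melanocyte genes, -0.82 for MAPK feedback, -0.63 for lymphoid, -0.20 for proteasome and -0.91 for MHC genes, the lowest of the melanomas, and 0.30 for muscle, 4.48 for oocyte and 4.35 for liver genes, the highest. It was lowest for mitfa (-0.40), tyr (0.11), sox10 (-0.59), etv4 (-0.90), atp6v1c1b (0.42), canx (-0.12), snap25b (-1.93), isg15 (-1.73), cox6b1 (-0.87), runx3 (-1.95), pfkpa (-1.05) and ppt1 (-0.48). It was highest for ldb3a (0.25), lyz (1.67), il17rd (0.90), ckmt2a (1.78), tmem38a (0.40), s100b (0.81) and pfkma (0.58). Melanoma 5 was highest for ndufb7 (0.80) and melanoma 2 for mhc1uda (0.046). In mutant skin, array 2 was highest for col9a2 (2.92) and lowest for krt97 (-1.83), nme2b.2 (-2.27) and the hybridisation control probe sets (-4.25). Mutant skin 6 was lowest for spry4 (-4.55) and trim63a (-1.79).

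The first pattern is the set of 7 arrays with high egg coat and oocyte transcripts, melanoma 6 among them. Ovarian tissue in the excised pieces may be the source: 16 germ cell genes that are not on the oocyte list had medians at least 1.04 log2 units (mutant skin 4) and up to 5.52 above the other 8 arrays, which lay between -0.27 and 0.50. The 7 arrays were chosen for high oocyte transcripts, so a rise of other germ cell genes was likely. It cannot tell ovarian tissue from another source of such RNA. No mutant skin array had a melanocyte level like melanoma 1 to 5, whose lowest lay 2.25 above the highest of mutant skin. This argues against an exchange of melanoma 6 with a tumour as rich in melanocyte transcripts as those 5. An exchange with a tumour mixed with other tissue stays open. Mutant skin 2 had the highest melanocyte level of mutant skin, -0.14, and the lowest muscle level, -0.56. Whether melanoma 6 is a skin sample or a tumour mixed with other tissue cannot be told apart. In 19.3% of 729 genes higher in melanoma 1 to 5 than in every mutant skin array, it also lay above every mutant skin array. Single mutant skin arrays left out lay above the other 5 in 2.04% to 39.6% of genes. Those genes were chosen anew without the array left out, and it had fewer arrays to exceed. Both tend to raise its share, so these shares are not strictly alike. The melanocyte level of melanoma 6, 0.092, lay above the highest of mutant skin, -0.14, by less than the mutant skin SD of 0.56. The labels give no sex and no group that could hold a biological explanation, so none was tested.

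The second pattern is the MHC genes: for mhc1ufa, mhc1uda and mhc2daa the 3 wild-type arrays lay outside the range of the other 12. Another haplotype of the MHC region in the wild-type fish might be the cause, and the test leaves it open: of 32 measured neighbours of psmb8a 0 set the wild-type arrays apart, against 2.03% of 8730 other genes (one-sided Fisher's exact p = 1), too few neighbours to differ from that share. The immunoproteasome gene psmb8a and those beside it were left out of that test as list members. They were higher in the wild-type arrays, as mhc1ufa and mhc1uda were, while mhc2daa was lower there. The gene psmb9a set the wild-type arrays apart (mean -0.48 against -2.94 in the others). With overlapping ranges psmb8a was at -1.04 against -3.20, psmb12 at -1.63 against -3.72 and psmb13a at -0.78 against -2.70. Other members of the list were lower in wild-type skin, such as psmb10 (-3.71 against -1.27, with overlapping ranges). The gene socs1a, which like mhc2daa lies on another chromosome, also set the wild-type arrays apart. As mhc1ufa and mhc1uda have no position in the gene table, only 1 called gene, vamp1a, is placed on the chromosome of psmb8a. A sequence variant under the probes of 1 probe set alone is argued against for mhc1uda. In limma 2 of its 2 probe sets had the sign of the gene at unadjusted p under 0.05. They changed by -4.71 and -1.67 in mutant against wild-type skin. A variant under both, or one adding to the larger change, therefore stays open. The other called genes with several probe sets, copb2 and wls, did not pass this check in each probe set (smallest changes 0.48 and -0.20). A variant also stays open for mhc1ufa and mhc2daa, which have 1 probe set each. The effect of the genotype, the group that the labels name, stays open and was not tested apart from the strain.

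The third pattern is the lower oxidative phosphorylation level in melanoma than in wild-type skin, -1.25 ± 0.42 (SE). Less muscle in the melanoma samples might account for it: with the muscle level as a covariate the difference was -0.28 ± 0.76, and 0 genes of the list remained lowered. For mutant skin, where the difference was -0.86 ± 0.42, the covariate left most of it, -0.65 ± 0.42, and between melanoma and mutant skin the muscle level differed by -4.18 and the oxidative phosphorylation level by -0.38. The call ended because the error grew while the estimate shrank, and the groups differ in muscle level, so the tumour itself and its muscle content cannot be told apart.

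Other splits of the same arrays were fitted for each count. For probe sets, chance can be excluded for melanoma against mutant skin (1673, highest of 100 splits otherwise 900, with 1 as large counting the real one) and against wild-type skin (2143, highest of 84 otherwise 1473, with 1 as large). For mutant against wild-type skin 3 of 84 splits, the real one included, gave 30 or more, the highest 6579. This share is under 0.05, the limit used for the splits, and by that limit alone chance would be excluded. The real split was not the highest, however. With the title number as a block the count was 0, in a fit with 2 residual degrees of freedom for a pairing the labels do not state. Chance is therefore not taken as excluded for the count of 30 probe sets. The splits tested this count and not its single genes. The split with 6579 calls set mutant skin 2 and 6 and wild-type skin 1 against the other skin arrays. Those 3 are the skin arrays with the highest oocyte levels, which points to a structure of the samples. For the called lists chance cannot be excluded. For 18 lists 8 of 100 splits gave as many and the highest other 20, for 15 lists 11 of 84 and 20, and for 6 lists 76 of 84 and 18. The median of the other splits was 11, 10 and 11 lists. Camera with the preset correlation thus called many lists under exchanged labels too. Its adjusted p-values above, however small, are to be read with that limit. For the 30 shared probe sets 1 of 100 splits of the 15 arrays was as large, the real one included, and the highest other was 3. These splits exchange the labels of all 3 groups at once. They therefore exclude chance only for the case that no group differs. They cannot tell whether the sharing comes from the use of the same 3 wild-type arrays in both comparisons.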

How the results depend on the processing

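The settings without the arrays with high oocyte transcripts, with the oocyte covariate, without probe sets matching several transcripts and with the probe set of largest SD were chosen after the data were seen. The planned filter at log2 above 6, the probe set with the highest mean and the alternative for linear values were not run, as the values are log2 and relative. Array quality weights did not converge fully. The cause of the differences below was not tested, except that settings with fewer arrays or 1 probe set per gene hold fewer values. Of 118 named gene results past the threshold, 105 stayed past it in every planned setting other than leaving out 1 array and the block, 84 in every fit without 1 array, 107 in every added setting and 75 in all. Of the probe sets called, 1666 of 1673, 2099 of 2143 and 29 of 30 were also called without melanoma 6. Signal over background is unknown in relative values, which limits what can be said of dim genes.

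For melanoma against mutant skin the 1673 probe sets became 4300 with array quality weights and 1112 with the probe set of largest SD. They became 2954 without the arrays with high oocyte transcripts and 2826 with the covariate. For melanoma against wild-type skin the 2143 became 8548 with weights and 4281 with the covariate. For mutant against wild-type skin the 30 became 1919 with weights, 12 with only the arrays of the 2 groups, 12 with the mean of a gene's probe sets, 13 with the largest SD, 47 without the ovarian arrays and 113 with the covariate. Called lists were 0, 0 and 0 with an estimated correlation. In the exact test they were 7 for melanoma against mutant skin and 0 for mutant against wild-type skin. The 30 shared probe sets became 1537 with weights, 11 with only the arrays of the 2 groups and 105 with the covariate. The median of the ribosomal list turned to -0.0068 and -0.092 with the covariate in the comparisons of melanoma with mutant and with wild-type skin.

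Leaving out 1 array gave 987 (melanoma 5) to 3101 (melanoma 6), 848 (wild-type skin 3) to 3097 (melanoma 6) and 15 (wild-type skin 3) to 54 (wild-type skin 1) probe sets, 13 to 20, 13 to 17 and 5 to 8 lists, and 15 to 49 shared probe sets (without wild-type skin 3 and 1). Beyond 1.5 times the count were also 992 without mutant skin 1, 1086, 1057 and 1076 without melanoma 1, 2 and 4, and 860 without wild-type skin 2.

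With the number in the titles as a block, for a pairing the labels do not state, the counts were 2469, 2482 and 0 (limma; 724 at unadjusted p under 0.05 for the last, with 2 residual degrees of freedom). Melanoma and mutant skin of the same number had correlations across probe sets of 0.092, -0.075, 0.45, 0.20, 0.39 and 0.70. These were taken after subtraction of each probe set's group mean, unlike the earlier correlations, which used the mean over all arrays. Melanoma 3, 5 and 6 were highest with their own number, and melanoma 1, 2 and 4 with another. This neither shows nor rules out pairs, and as the labels state none, the numbers were not taken as pairs.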
